A study of Mus musculus with 24 samples.

How the data were processed

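PolyA RNA of 13 mouse hearts (100-base paired reads per the labels) and small RNA of 11 of the same hearts (50-base single reads) had been sequenced; 24 samples from 13 animals were used and none was left out. Per the labels, the authors used FastQC 0.11.2, STAR 2.40, Cufflinks 2.2.1 and Cuffdiff with mouse build mm9; the step each tool served is not given in the sources used here. The deposited values are FPKM (fpkm), fragments scaled by transcript length and mapped fragments, in 1 table for each kind of library with 1 column per library. The annotation, the filters and any scaling between libraries are not given in the sources used here, and the medians of the polyA columns differed. Read numbers are not given in the sources used here, so the depth per sample and counting errors are unknown, and a listed 0 cannot be told apart from a gene that was not quantified. Among the 23998 polyA symbols, 93.8% were current symbols and 99.4% current symbols or synonyms in the reference annotation, which was used for names only.

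Libraries were grouped by the sample labels into wild type with control virus, mutant without virus, mutant with control virus and mutant with shRNA. The genotype field of the labels was the same for all samples, so genotype was taken from the sample names. Values were taken as deposited, as log2(FPKM + 1), and genes with a mean of at least 1 FPKM over all libraries of an assay were tested. One linear model over the 4 groups was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend, two-sided), and genes passed at a Benjamini-Hochberg adjusted p under 0.05 within a comparison, with no fold minimum. Comparisons were shRNA against control virus, mutant against wild type, control virus against no virus, shRNA against wild type and shRNA against no virus for polyA RNA, and the first 3 for small RNA.

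A fixed set of 37 lists of genes and 7 of small RNA genes covered pathways and cell types of the heart. Lists with at least 5 tested genes (36) were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry, which asks only whether a list moves one way. List tests were planned for the first 3 comparisons; those for shRNA against wild type and against no virus were added after seeing the data. Lists overlap, as Col1a1, Gdf15 and Kcnj3 each stand in more than 1. Of 1 list, mitochondrially encoded transcripts, and of the small nucleolar RNA list, 0 genes were in the tables. Genes named are Myl2 and any row for the transgene or the virus, up to 10 genes each way with the largest changes among those that passed with groups that did not overlap, leaving out genes without an assigned name (or up to 10 with the smallest p where too few passed), up to 4 members of each list that passed with the smallest p, and a fixed set of cardiac stress, matrix and calcium genes; for small RNA up to 5 each way and a fixed set of cardiac microRNAs. The opposition of the mutant and shRNA differences was measured across genes by correlation and covariance, beside 100 simulations of unchanged groups that share libraries as the real ones do.

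These choices, the lists and most alternatives were made before the data were examined. Alternatives fixed at that point were a smaller pseudocount, a stricter and no filter on low values, quantile normalization, equal FPKM totals, a fit on the compared groups alone, robust eBayes, the replicate number as a block where 2 groups share numbers, and leaving out each library in turn, and for the opposition a version with no shared library. Chosen after seeing the data were alignment of the libraries on their median over genes above 0 in every library, sex as a covariate (a library with Ddx3y above 5 FPKM was taken as male), leaving out shRNA replicate 8 together with these or where it entered only the shared spread, and for small RNA a pseudocount of 1000 with a mean of 10000 FPKM. The position of a library is its projection on the line between 2 group means. It was taken over the 500 polyA or 50 small RNA genes with the smallest p between these groups by limma. Genes with a larger group difference weigh more in it.

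The procedure was tested on simulated data with the same groups and spread. Simulated values were independent between genes, with no scale difference between libraries and no outlying library, so the rates below may not hold for the real libraries. With 200 genes changed among 12980, the limma test for shRNA against control virus found 3.73% of genes changed 1.5-fold, 36.1% of those changed 2-fold and 97.9% of those changed 4-fold, with 4.66% of its calls false. For mutant against wild type these were 2.09%, 26.1%, 96.1% and 6.26%. In small RNA with 280 genes, 38% and 35% of genes changed 4-fold were found. A list of 20 genes shifted by 0.5 on the log2 scale was found in 20 of 20 draws, and 1 of 700 other lists was called, in data simulated without correlation between genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.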

Results

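Heart RNA of 13 transgenic mice on a CD1 background was measured as polyA RNA in 13 libraries and as small RNA in 11 libraries. All mice carried a human MYL2 transgene, which codes for the ventricular regulatory light chain of myosin, in its normal form (called wild type here) or in a mutated form. An adeno-associated virus of serotype AAV9 was given at 3 days of age and hearts were taken at 4 months. The polyA libraries fell into 4 groups: wild type with control virus (3), mutant without virus (3), mutant with control virus (3) and mutant labelled with the virus that carries the M7.8L shRNA (4). The corresponding small RNA groups held 2, 2, 3 and 4 libraries, from animals that also gave a polyA library.

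Expression was given as fragments scaled by transcript length and mapped fragments (FPKM), so read depth is unknown and no counting interval can be given. FPKM totals ran from 580948 to 1701500 in the polyA libraries and from 1491420000 to 1960090000 in the small RNA libraries. Of 23998 genes in the polyA table, 12980 reached a mean of 1 FPKM and were tested, and of 568 small RNA genes 280 did. The polyA libraries differed in scale: their median log2 shift ran from -0.54 (untreated mutant replicate 10) to 0.80 (shRNA replicate 8), while that of the small RNA libraries ran from -0.042 to 0.14. Changes are therefore given as deposited and, chosen after seeing the data, relative to that shift after alignment of the library medians (written "aligned"). Group values are means ± SD over the group sizes above, and folds come from the mean difference of log2(FPKM + 1) values. For genes near 0 FPKM in a group, the added 1 shrinks the fold below the ratio of the printed means.

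The row of the table named for human MYL2, hMyl2, was 228.8, 419.6 and 317.2 FPKM in shRNA replicates 5, 6 and 7 and was listed at 0 in the other 10 polyA libraries, including every library of a mutant without shRNA and of the wild type. The row named shRNA was listed at 0 in all 13. The hMyl2 row was thus above 0 in 3 of 13 libraries, and whether it measures the transgene was not tested. Neither row shows a lower transgene level in the hearts labelled shRNA. These rows thus settle neither the treatment nor the genotype of the hearts labelled shRNA, which were both taken from the labels. Other expression that bears on the genotype, such as that of Six3, is given below. Whether reads of the human transgene were counted in the mouse row Myl2 is not given in the sources used here. Mouse Myl2 was 26212 ± 2479 FPKM in wild-type and 12369 ± 1785 in untreated mutant hearts. It was 12074 ± 2001 in mutant hearts with control virus and 33482 ± 13227 in hearts labelled shRNA. It fell in mutant against wild-type hearts with control virus (2.18-fold, adjusted p = 0.0393) and rose with the shRNA label (2.65-fold, adjusted p = 0.00294), but neither passed after alignment (adjusted p = 0.0746 and 0.0785). Against untreated mutant hearts it rose with the shRNA label (2.58-fold, adjusted p = 0.00172, aligned 0.190). It did not pass between control virus and no virus (adjusted p = 0.972) or between the shRNA label and wild type (adjusted p = 0.541).

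Library shRNA replicate 8 lay apart from the others of its group. On an axis of 500 genes set to 0 at wild-type and 1 at untreated mutant hearts, shRNA replicates 5, 6 and 7 lay at -0.12, -0.12 and -0.097 and replicate 8 at 0.871 with libraries aligned (0.687 as deposited), while mutant libraries with control virus lay between 0.901 and 0.993. By Y-linked genes, the 3 mutant hearts with control virus and shRNA replicate 8 came from females, and shRNA replicates 5, 6 and 7 from males. Of the other groups 2 untreated mutant and 2 wild-type hearts were male and 1 of each was female. Sex thus moved with the shRNA label and with replicate 8. The row Rn45s did so too, listed at 0 in replicate 8 and the 3 mutants with control virus and at 16277 to 22526 FPKM in replicates 5 to 7. It was also 0 in wild-type replicate 2 and untreated replicate 11, and 8645 to 18965 FPKM in the remaining libraries. What sets this row apart was not tested. Wild-type replicate 3, taken as male, had 8.31 FPKM of Xist. The other male libraries had 0.176 to 0.965 FPKM of it and the female libraries 37.5 to 123.7. This wild-type library also had 66.3 FPKM of Alb, coding for albumin, against at most 13.4 FPKM in any other library. The reason for these values was not tested. The number of genes that passed in each comparison is also given without replicate 8. Leaving it out was set in advance where the shRNA group is compared and was added after seeing the data where it enters only the shared spread.

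**Figure D1:**
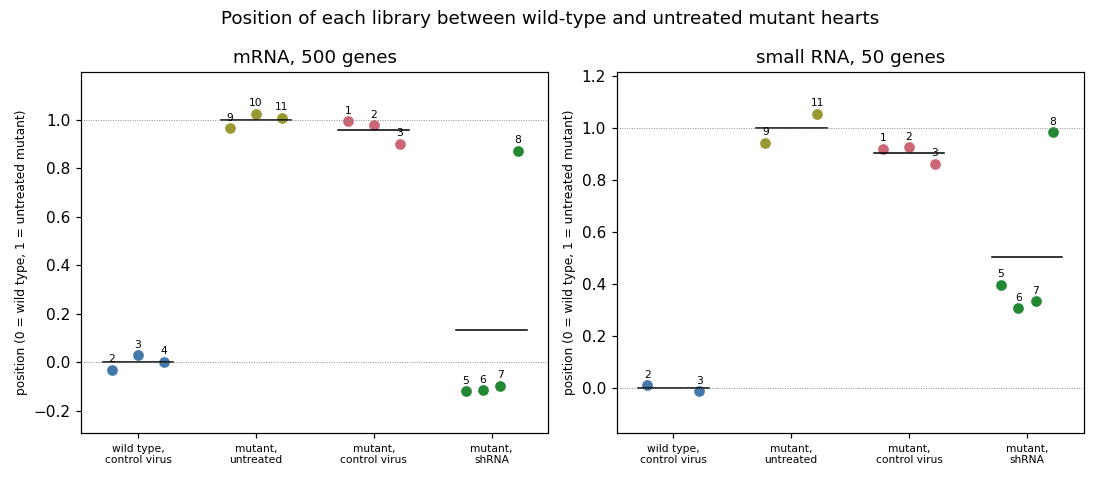
Position of each polyA library (left, 500 genes, median-aligned) and each small RNA library (right, 50 genes) between wild-type hearts at 0 and untreated mutant hearts at 1. Points are libraries with their replicate numbers and lines are group means. The genes were chosen between the groups that define 0 and 1. Replicate 8 of the shRNA group lies at 0.871 and 0.984; with low small RNA values kept it lies at 0.381, beside replicate 6 of its group.

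Mutant and wild-type hearts that both had control virus were compared for differences between the genotypes named in the labels under the same vector; sex was uneven between them. Several genes of the fetal and stress programme were higher in the mutant: Nppa (35009.6 ± 14546 against 2089 ± 1217 FPKM), coding for atrial natriuretic peptide, rose 17.3-fold (adjusted p = 0.0138), Nppb (3022 ± 1154 against 426 ± 126 FPKM), coding for brain natriuretic peptide, rose 6.94-fold, and Myh7 (1766 ± 169 against 334 ± 78.6 FPKM), the slow myosin heavy chain, rose 5.36-fold. The stress cytokine Gdf15 (253 ± 31.9 against 6.51 ± 4.27 FPKM) rose 38.0-fold (adjusted p = 0.00644). Ankrd1, a stress-responsive sarcomere protein, was 3.22-fold higher without passing (adjusted p = 0.0677, aligned 0.0252), and skeletal actin Acta1 was 1404 ± 161 against 1814 ± 1529 FPKM (adjusted p = 0.971). Of 19 tested genes of the hypertrophy list, 10 rose, 2 fell and 7 did not pass (11 and 2 adjusted over the list alone). Rcan1, a calcineurin target, rose 4.93-fold and Uchl1, a deubiquitinase, 8.81-fold. The list test gave an adjusted p of 8.17e-07, and 0.375 with an estimated correlation. Myh6, the adult myosin heavy chain, was listed at 0, 12709 and 11042 FPKM in wild-type and at 3887, 4612 and 0 in mutant libraries, so no fold is given.

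The matrix list passed upward in mutant hearts by camera, but not with an estimated correlation (adjusted p = 0.375). The collagens Col1a1 (185 ± 17.2 against 37.2 ± 6.34 FPKM) and Col3a1 (409 ± 100.2 against 62.0 ± 11.9 FPKM) rose 4.91-fold and 6.48-fold, the matricellular Postn (224 ± 124 against 21.6 ± 6.19 FPKM) 9.19-fold, and Ctgf (893 ± 299 against 85.7 ± 31.2 FPKM), a growth factor of fibrosis, 10.3-fold (adjusted p = 0.00897). Timp1, an inhibitor of matrix proteases, and Mfap4, a microfibril protein, rose 17.0-fold and 16.9-fold, and Thbs1 and Comp 5.89-fold and 6.43-fold. Of 42 tested genes of the matrix and fibrosis list 26 rose, 16 did not pass and 0 fell (38 rose adjusted over the list alone, and 38 after alignment; limma). Its median was 1.74 on the log2 scale, 1.90 aligned, with an adjusted p of 2.73e-30, and 0.375 with an estimated correlation. Among 18 fibroblast markers 5 rose (8 over the list alone, 13 aligned), which include Col1a2 (3.41-fold) and 3 genes named above (adjusted p = 3.93e-09, and 0.375 with an estimated correlation).

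Lists of immune genes passed upward by camera, most with few members that passed, and none did with an estimated correlation (adjusted p = 0.375 to 0.512). Of 22 macrophage markers 6 rose and 1 fell (14 and 1 adjusted over the list alone), with Mpeg1, Ctss, Cd52 and Ccr2 up 4.92-fold, 4.78-fold, 7.18-fold and 5.08-fold (list adjusted p = 3.93e-09, and 0.407 with an estimated correlation). Of 19 antigen presentation genes 6 rose (8 over the list alone): the class II genes H2-Eb1, H2-Ab1 and H2-Aa rose 5.80-fold, 5.62-fold and 5.42-fold, and the class I gene H2-K1 3.61-fold (list adjusted p = 2.67e-09). Of 24 inflammatory genes 6 rose (7 over the list alone), among them the acute phase gene Serpina3n (9.73-fold) and the chemokine Ccl8 (8.82-fold; list adjusted p = 1.02e-09). S100a8 (3.47-fold) was the only one of 8 neutrophil and mast cell markers to pass (1 over the list alone; list adjusted p = 0.00416, and 0.0622 aligned). Of 6 lymphocyte markers 0 passed over all genes and 1 over the list alone (list adjusted p = 0.000708; Nkg7 2.98 ± 1.57 against 0.373 ± 0.391 FPKM). Each of these 4 lists had an adjusted p of 0.375 with an estimated correlation. Of 35 interferon genes 0 passed, over the list alone as well, by limma, although the list did (adjusted p = 1.15e-06, and 0.512 with an estimated correlation; Bst2 97.4 ± 40.4 against 42.0 ± 10.2 FPKM).

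Lists of energy metabolism passed downward in mutant hearts by camera, but not with an estimated correlation (adjusted p = 0.375 to 0.407). Of 31 fatty acid oxidation genes 21 fell and 0 rose (26 fell adjusted over the list alone), with the carnitine enzyme Cpt2 (102 ± 29.2 against 298 ± 9.90 FPKM) down 2.99-fold and Hadh, Acsl1 and Etfdh 2.81-fold, 2.97-fold and 2.95-fold. Of 20 genes of the tricarboxylic acid cycle 17 fell (20 over the list alone), with Idh2 (789.9 ± 87.3 against 2711 ± 508 FPKM) down 3.40-fold. Of 47 nuclear genes of oxidative phosphorylation 17 fell (46 over the list alone, 13 aligned), among them Cox7a1 (2.82-fold), Sdha (2.37-fold) and Uqcrfs1 (2.19-fold). Their median log2 differences were -1.28, -1.03 and -0.88, and aligned -1.12, -0.87 and -0.72. The adjusted p values were 2.92e-11, 3.41e-11 and 5.64e-15, and 0.375, 0.375 and 0.407 with an estimated correlation.

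Lists of excitation and contraction passed downward by camera, with most members not passing over all genes, and none did with an estimated correlation (adjusted p = 0.375 to 0.592). The potassium channel gene Kcnj3 (1.36 ± 0.612 against 44.5 ± 1.74 FPKM) fell 19.8-fold, and Kcnv2, Kcnj2 and Kcnj12 fell 5.86-fold, 2.74-fold and 2.13-fold; of 22 ion channel genes 9 fell and 1 rose (14 and 1 adjusted over the list alone; list adjusted p = 1.35e-05, and 0.375 with an estimated correlation). Atp2a2 (3310.3 ± 604 against 8519 ± 821 FPKM), coding for the calcium pump SERCA2, fell 2.59-fold (adjusted p = 0.0157), Pln (3323 ± 666 against 6586 ± 345 FPKM), its regulator phospholamban, 2.01-fold, and Hrc, a calcium binding protein of the sarcoplasmic reticulum, 3.74-fold. Of 18 calcium handling genes 5 fell and 1 rose (9 and 1 over the list alone; list adjusted p = 0.0123, and 0.512 with an estimated correlation). Of 25 sarcomere genes 5 fell (6 fell and 1 rose over the list alone), including the titin cap Tcap (4.73-fold) and cardiac troponin Tnni3 (2.46-fold; list adjusted p = 0.0115, and 0.592 with an estimated correlation). Of 6 skeletal muscle markers Casq1, Cacna1s and Tnnt1 fell (5.38-fold, 3.29-fold and 2.02-fold; 3 over the list alone; list adjusted p = 0.0469, 0.0716 aligned and 0.423 with an estimated correlation). Of 23 clock genes 11 fell and 1 rose (12 and 1 over the list alone), with the output genes Hlf, Tef, Usp2 and Per3 down 3.06-fold, 2.80-fold, 2.80-fold and 2.53-fold (list adjusted p = 0.00912, and 0.512 with an estimated correlation).

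Several stress lists passed upward by camera with mixed members, and none did with an estimated correlation (adjusted p = 0.375 to 0.651). In the unfolded protein and integrated stress list 6 of 28 rose and 2 fell (9 and 2 adjusted over the list alone), with Chac1, a glutathione-degrading enzyme, up 4.26-fold and the lipoprotein receptor Vldlr down 2.25-fold (list adjusted p = 7.17e-06, and 0.496 with an estimated correlation). Of 27 immediate early genes 7 rose (10 over the list alone), with Junb, Atf3, Egr2 and Fos up 2.65-fold, 2.37-fold, 3.79-fold and 3.75-fold (list adjusted p = 8.67e-09, and 0.375 with an estimated correlation). The oxidative stress list passed upward (adjusted p = 0.00303, and 0.592 with an estimated correlation) although 3 of its 23 genes fell and 1 rose (3 and 5 over the list alone): the mitochondrial enzymes Sod2 and Prdx3 and the transferase Gsta3 fell, and secreted Gpx3 rose 4.13-fold. In the p53 list (22 genes) Cdkn1a and Phlda3 rose 3.84-fold and 4.56-fold while Ccng1 and Gadd45a fell, 2 up and 3 down over all genes and over the list alone (list adjusted p = 0.0318, and 0.651 with an estimated correlation). The cell cycle list (26 genes) passed upward (adjusted p = 4.07e-05, and 0.512 with an estimated correlation) while its 1 gene that passed, Cenpf, fell 4.78-fold (1 over the list alone). Of 13 atrial markers 3 rose and 2 fell (5 and 2 over the list alone; list adjusted p = 0.0469, 0.351 aligned and 0.512 with an estimated correlation), and of 10 mesothelial markers Krt18 and Aldh1a2 rose 13-fold and 4.37-fold (2 up and 1 down over the list alone; list adjusted p = 0.00181, and 0.375 with an estimated correlation).

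Among the genes with the largest changes, Sprr1a (35.4 ± 9.85 against 0.216 ± 0.204 FPKM), Lgals3 (101 ± 70.1 against 3.10 ± 0.781 FPKM), coding for galectin 3, and Gpnmb (36.0 ± 4.52 against 1.43 ± 0.0938 FPKM) rose 29.5-fold, 21.6-fold and 15.2-fold, and the signalling gene Wnt16 was 19.2 ± 6.40 FPKM and listed at 0 in all wild-type libraries. The homeobox gene Six3 was 0 to 0.0791 FPKM in wild-type libraries and 13.6 to 27.6 FPKM in mutant libraries without shRNA. Mutant hearts with control virus were 25.0-fold above wild type. In the hearts labelled shRNA, Six3 was 0, 0.0913 and 0 FPKM in replicates 5, 6 and 7, as in wild type, and 60.6 in replicate 8, and its neighbour Six3os1 was 0, 0.0749, 0 and 13.2 FPKM. The genes Mylk4 (11.4 ± 0.863 against 135 ± 38.1 FPKM), Rpl3l (67.4 ± 32.5 against 579.6 ± 24.9 FPKM) and Gpt (6.68 ± 0.742 against 64.1 ± 2.42 FPKM), a muscle kinase, a muscle ribosomal protein and alanine aminotransferase, fell 10.7-fold, 9.37-fold and 8.5-fold. Smco1, Myot, Fbp2, Penk and Efnb3 fell 7.29-fold to 12.1-fold.

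In all, 1233 of 12980 genes passed limma between mutant and wild-type hearts with control virus, 279 higher and 954 lower; the median of all genes was -0.14 on the log2 scale. After alignment 3144 passed, 1672 higher and 1472 lower, and 1147 passed both ways in the same direction. The groups did not overlap for 5459 genes (42.1%, where chance gives 10%). By camera 24 of 36 lists passed, 16 upward and 8 downward, 0 with an estimated correlation (smallest adjusted p = 0.375), 2 by fry (0 upward, 2 downward) and 23 after alignment. Of the 24 lists 21 passed both ways in the same direction; the atrial, the neutrophil and mast cell and the skeletal muscle lists did not pass aligned, and the endothelial and smooth muscle lists passed downward only aligned. Lists that did not pass covered basement membrane, glycolysis, the small RNA pathway, heat shock, proteasome, insulin signalling, endothelium, smooth muscle, red cells, adipocytes, nerve and sex-linked genes. With sex as a covariate 126 genes passed, and 1340 (638 higher, 702 lower) when shRNA replicate 8 was left out as well. The count was 344, 328 and 369 without wild-type replicate 2, 3 or 4, 179 and 367 without mutant control-virus replicate 1 or 3, and 2755 (1102 higher, 1653 lower) without shRNA replicate 8, which enters only the shared spread.

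**Figure D2:**
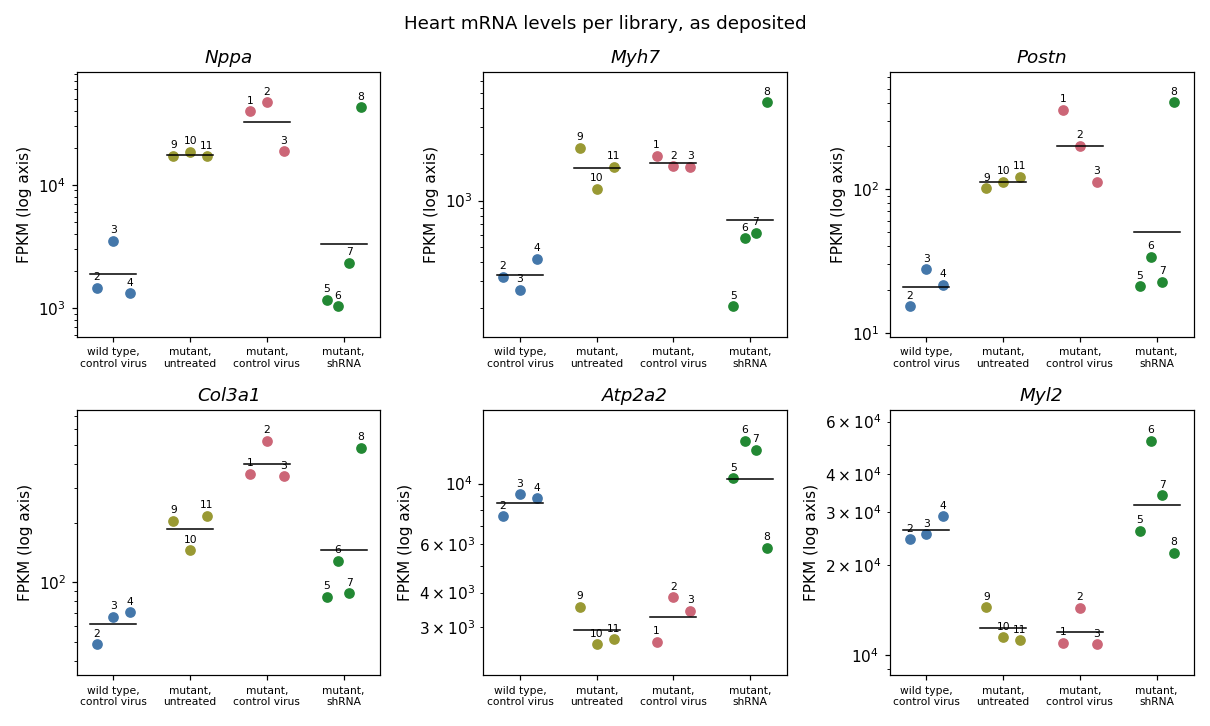
FPKM per polyA library on a log axis for 6 genes in the 4 groups; points are libraries with their replicate numbers and lines are geometric means. Nppa lay between 18713 and 46679 FPKM in mutant hearts with control virus and between 1316 and 3492 FPKM in wild-type hearts. Replicate 8 of the shRNA group, at 42676 FPKM, lay far above replicates 5 to 7 of its group (1033 to 2315 FPKM).

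Mutant hearts with control virus and without virus were compared for differences that go with the vector. Sex was uneven between them, with 0 of 3 hearts male with control virus and 2 of 3 without virus. Differences due to the vector and to sex are thus mixed. No gene passed (0 of 12980 by limma, 572 at an unadjusted p under 0.05, smallest adjusted p = 0.771), but 181 did (146 higher, 35 lower) when the 2 groups were fitted alone. The smallest p values belonged to genes that were higher with the virus in every library: Ifitm1 (10.8 ± 4.03 against 3.30 ± 0.775 FPKM), an interferon-induced membrane protein, Them6 (18.2 ± 4.66 against 7.40 ± 2.64 FPKM), Psca (7.82 ± 2.06 against 0.865 ± 0.304 FPKM), Lrrc10 (432 ± 43.6 against 202 ± 30.5 FPKM), a cardiac protein, and Comp (19.0 ± 9.62 against 4.20 ± 1.83 FPKM), a matrix protein. Nt5dc2, H2-Q1, H2-Q2, Vaultrc5 and the phosphatase Dusp1 were 1.99-fold to 5.03-fold higher, and none of these 10 genes passed. H2-Q genes are close copies of one another, so reads can be shared between them. The groups did not overlap for 1954 genes (15.1%, where chance gives 10%).

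By camera 6 of 36 lists passed between control virus and no virus, and 0 by fry. With an estimated correlation the sex-linked list passed (adjusted p = 0.0271) and the other 5 did not (adjusted p = 0.982 each). Upward were the matrix list (42 genes; adjusted p = 0.0358; Col3a1 409 ± 100.2 against 189.96 ± 38.8 FPKM), antigen presentation (19; adjusted p = 0.0161; B2m 1649.6 ± 1195 against 766 ± 83.1 FPKM) and oxidative phosphorylation (47; adjusted p = 0.00115; Cyc1 1002 ± 131 against 716 ± 224 FPKM). Downward were the hypertrophy list (19; adjusted p = 0.0274; Xirp2 352 ± 9.18 against 927 ± 428 FPKM), heat shock (18; adjusted p = 0.0304; Hspa1a 42.1 ± 12.5 against 72.6 ± 30.8 FPKM) and sex-linked genes (6; adjusted p = 4.14e-05; Ddx3y 0.0181 ± 0.0314 against 33.3 ± 28.3 FPKM). No member passed over all genes by limma, and over the list alone 1 matrix gene, Comp, did. The medians of the hypertrophy and heat shock lists were above 0 (0.14 and 0.058) and so were their means (0.087 and 0.028), against the downward test; the median of all genes was 0.23. After alignment 4 lists passed, of which the matrix and antigen presentation lists were among the 6; oxidative phosphorylation, hypertrophy, heat shock and sex-linked genes did not (adjusted p = 0.108, 0.254, 0.0847 and 0.170). Without shRNA replicate 8, which enters only the shared spread, 7 genes passed, and 1 did without mutant control-virus replicate 2. The number of lists was 11 without untreated replicate 10, 10 and 12 without control-virus replicate 1 or 3, and 10 without shRNA replicate 8. It was 15 with sex as a covariate, with which the matrix list turned downward and passed by camera (adjusted p = 0.0146). With sex as a covariate and shRNA replicate 8 left out, the matrix list did not turn.

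Hearts labelled shRNA and mutant hearts with control virus were compared to see what the allele-directed shRNA changed in the mutant heart. Natriuretic peptide genes were lower with the shRNA label: Nppa (11797 ± 20594 against 35009.6 ± 14546 FPKM) fell 9.87-fold (adjusted p = 0.00870) and Nppb (1745 ± 2601 against 3022 ± 1154 FPKM) 3.95-fold (adjusted p = 0.0463). Their groups overlapped, since replicate 8 had 42676 FPKM of Nppa against 1033 to 2315 FPKM in replicates 5 to 7. Gdf15 (74.6 ± 133 against 253 ± 31.9 FPKM) fell 13.5-fold, Uchl1 (15.3 ± 23.8 against 80.2 ± 5.52 FPKM) 10.4-fold and Acta1 (436 ± 347 against 1404 ± 161 FPKM) 4.27-fold (adjusted p = 0.0184). Myh7 was 1439 ± 1959 against 1766 ± 169 FPKM and Ankrd1 5409 ± 6657 against 8642 ± 2609.6 FPKM, and neither passed (adjusted p = 0.130 and 0.0634); both did after alignment (adjusted p = 0.0485 and 0.0230). Hopx, a cardiac transcription cofactor, and Myh7b rose 2.90-fold and 2.44-fold. Of the 19 hypertrophy genes 10 fell, 3 rose and 6 did not pass (13 and 3 adjusted over the list alone; list adjusted p = 4.73e-13, and 0.50 with an estimated correlation). Without replicate 8 the folds of Nppa, Nppb, Gdf15 and Uchl1 were 23.2-fold, 7.81-fold, 33.1-fold and 19.6-fold. Myh7 and Ankrd1 then passed (4.23-fold and 4.07-fold lower). Myh6 was 11075, 13491, 17461 and 7226 FPKM in the shRNA libraries against 3887, 4612 and 0.

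The matrix list passed downward with the shRNA label by camera, but not with an estimated correlation (adjusted p = 0.50). Postn (119.9 ± 188 against 224 ± 124 FPKM) fell 3.88-fold, Col1a1 (97.7 ± 109 against 185 ± 17.2 FPKM) 2.71-fold, Col3a1 (196 ± 192 against 409 ± 100.2 FPKM) 2.72-fold and Ctgf (337 ± 471 against 893 ± 299 FPKM) 4.92-fold (adjusted p = 0.0375, 0.0260, 0.0174 and 0.0116), each with groups that overlapped. Tnc, Thbs1 and Timp1 fell 3.53-fold, 3.40-fold and 8.35-fold. Of the 42 matrix genes 16 fell, 26 did not pass and 0 rose (16 adjusted over the list alone), and 37 fell after alignment and 37 without replicate 8. The median was -1.07 on the log2 scale, -1.58 aligned (list adjusted p = 2.01e-31, and 0.50 with an estimated correlation). Of 18 fibroblast markers 3 fell (3 over the list alone, 13 aligned; Mfap4 5.08-fold; list adjusted p = 8.16e-10, and 0.50 with an estimated correlation). Without replicate 8 the folds of Postn, Col1a1, Ctgf, Timp1 and Mfap4 were 7.67-fold, 4.24-fold, 8.93-fold, 17.6-fold and 10.8-fold.

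Lists of energy metabolism passed upward with the shRNA label by camera, but not with an estimated correlation (adjusted p = 0.50 each). All 47 genes of oxidative phosphorylation rose (47 adjusted over the list alone, 32 aligned), with Sdhb (2774 ± 877 against 883 ± 153 FPKM) up 3.05-fold and Sdha, Cox8b and Ndufs4 up 2.90-fold, 3.25-fold and 2.77-fold. All 20 genes of the tricarboxylic acid cycle rose (20 over the list alone, 16 aligned), with Idh2 (3842 ± 1572 against 789.9 ± 87.3 FPKM) up 4.54-fold. Of 31 fatty acid genes 28 rose (28 over the list alone; 23 rose and 1 fell aligned), among them Lpl (4529.9 ± 1467 against 1192 ± 222 FPKM), lipoprotein lipase, 3.68-fold, and the coactivator Ppargc1a 2.64-fold. The aligned medians were 0.81, 0.81 and 1.04 on the log2 scale, beside 1.33, 1.34 and 1.57 as deposited. Without replicate 8 the numbers that rose were 47, 20 and 28. The list adjusted p values were 4.75e-15, 8.47e-10 and 1.17e-08 by camera, and 0.50 each with an estimated correlation.

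Lists of excitation and contraction passed upward with the shRNA label by camera, and none did with an estimated correlation (adjusted p = 0.50 to 0.700). Fewer members passed after alignment than as deposited. Atp2a2 (10978 ± 3802 against 3310.3 ± 604 FPKM) rose 3.17-fold and Pln (9672 ± 2882 against 3323 ± 666 FPKM) 2.85-fold (adjusted p = 0.00114 and 0.00114), and Kcnj3 (49.1 ± 30.4 against 1.36 ± 0.612 FPKM), Kcnj2 and Kcnip2 rose 14.7-fold, 3.58-fold and 2.90-fold. Of 22 ion channel genes 14 rose (17 adjusted over the list alone, 9 aligned; list adjusted p = 0.00461, and 0.50 with an estimated correlation). Of 18 calcium handling genes 14 rose and 1 fell (15 and 1 over the list alone; 5 and 2 aligned; list adjusted p = 0.0172, and 0.631 with an estimated correlation). Of 25 sarcomere genes 18 rose and 1 fell (18 and 1 over the list alone; 4 and 2 aligned), with Tcap up 4.72-fold and Myom2 2.79-fold (list adjusted p = 0.00937, and 0.635 with an estimated correlation), a list that turned downward without passing under quantile normalization (adjusted p = 0.816). Of 20 endothelial markers 12 rose (15 over the list alone; 7 rose and 1 fell aligned), with Cdh5, Kdr and Tie1 up 2.34-fold, 2.08-fold and 2.19-fold (list adjusted p = 0.0214, and 0.700 with an estimated correlation). Without replicate 8 the fold of Kcnj3 was 28.3-fold.

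Immune and stress lists passed downward by camera with few members that passed, and none did with an estimated correlation (adjusted p = 0.50 each). Of 24 inflammatory genes 2 fell (2 adjusted over the list alone), Ccl8 8.09-fold and Serpina3n 5.49-fold. Of 19 antigen presentation genes H2-Ab1, H2-Eb1 and H2-Q7 fell 2.70-fold, 2.70-fold and 2.41-fold (0 over the list alone, 12 aligned), and of 35 interferon genes Zbp1 fell 3.30-fold (0 over the list alone, 9 aligned). Of 22 macrophage markers the 1 that passed, the scavenger receptor Cd163, rose 2.15-fold (1 over the list alone), while 12 fell and 1 rose after alignment and 18 fell and 1 rose without replicate 8. Of 6 lymphocyte markers 0 passed by limma, over the list alone as well (Nkg7 1.19 ± 2.15 against 2.98 ± 1.57 FPKM), and the list did not pass aligned (adjusted p = 0.0807). Of 18 heat shock genes Hsph1 and Hsp90aa1 fell 2.71-fold and 2.62-fold and Hspb6 rose 1.99-fold (0 over the list alone; 10 fell aligned), and of 26 cell cycle genes Cenpa rose 1.79-fold (0 over the list alone; 9 fell aligned). The 7 lists had adjusted p values of 1.87e-08, 1.17e-11, 2.03e-09, 4.79e-11, 0.000507, 2.42e-05 and 1.62e-06 in this order, and 0.50 each with an estimated correlation. With replicate 8 left out, the folds of Ccl8, Serpina3n, Zbp1, Hsph1 and Hsp90aa1 were 15.6-fold, 9.09-fold, 5.18-fold, 4.10-fold and 4.17-fold.

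For 5 further lists that passed downward by camera, and not with an estimated correlation (adjusted p = 0.50 to 0.635), the median lay above 0, as did that of all genes (0.47). The unfolded protein list had a median of 0.15 and a mean of -0.19: 5 of 28 rose and 6 fell, the same over the list alone, with Vldlr and Herpud1 up and Gdf15 down (list adjusted p = 0.000105, and 0.592 with an estimated correlation). In the oxidative stress list (median 0.038, mean -0.064) 5 of 23 rose and 2 fell, the same over the list alone, with Sod2 and Prdx3 up 2.89-fold and 2.39-fold (list adjusted p = 0.00138, and 0.635 with an estimated correlation). Immediate early genes (median 0.29, mean 0.25) had 3 of 27 up, Btg2, Nr4a2 and Nr4a1, and 2 over the list alone (list adjusted p = 0.0412, and 0.635 with an estimated correlation). Atrial markers (median 0.10, mean -0.13) had 5 of 13 up and 4 down, the same over the list alone, with Sln down 2.4-fold and Stk39 up 2.04-fold (list adjusted p = 0.0121, and 0.50 with an estimated correlation). Mesothelial markers (median 0.30, mean -0.072) had Krt18 down 7.60-fold and Efemp1 up 3.03-fold of 10, the same over the list alone (list adjusted p = 0.00828, and 0.50 with an estimated correlation). Aligned, the 5 medians were below 0, from -0.48 to -0.079, and the immediate early, atrial and mesothelial lists did not pass (adjusted p = 0.147, 0.412 and 0.244).

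Among the largest changes, Mylk4 (129.6 ± 70.9 against 11.4 ± 0.863 FPKM), Gpt (92.4 ± 57.4 against 6.68 ± 0.742 FPKM), Fah (87.6 ± 52.0 against 7.14 ± 0.752 FPKM) and Ptprn2 (10.7 ± 7.19 against 0.0678 ± 0.0354 FPKM) rose 8.91-fold, 9.13-fold, 8.77-fold and 8.18-fold; Lrrc4b, Efnb3, Retnla and Scd4 rose 12.2-fold, 11.4-fold, 10.8-fold and 10.5-fold. Wnt16, Dusp4, Dok5, Kcnj14 and Ppp2r2c fell 10.2-fold, 5.74-fold, 5.17-fold, 4.71-fold and 4.36-fold. Rps2 rose 14.1-fold and did not pass aligned (adjusted p = 0.0875), Rpl26 and Eif3j2 fell 10.6-fold and 8.58-fold, and Trim12a was 7.28 ± 0.616 FPKM with control virus and listed at 0 in all 4 shRNA libraries. Leaving out replicate 8, the folds of Gpt, Fah, Ptprn2, Lrrc4b, Efnb3, Retnla, Wnt16 and Ppp2r2c were 15.3-fold, 13.4-fold, 13.9-fold, 19.5-fold, 19.1-fold, 20.2-fold, 17.1-fold and 6.93-fold. The genes Rps2, Rpl26, Eif3j2 and Trim12a have close copies elsewhere in the genome, and how shared reads were assigned to them is not given in the sources used here; Gapdh, an abundant glycolytic gene with many copies, was listed at only 0.752 to 1.92 FPKM over all libraries.

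In all, 4545 of 12980 genes passed limma, 4330 higher and 215 lower with the shRNA label. After alignment 3128 passed, 1510 higher and 1618 lower, and 1725 passed both ways in the same direction; the share that was higher went from 95.3% to 48.3%. Without shRNA replicate 8 the count was 5113 (3952 higher, 1161 lower), and 6254 (3089 and 3165) with alignment as well. The groups did not overlap for 4047 genes (31.2%, where chance gives 5.71%). By camera 22 of 36 lists passed, 7 upward and 15 downward, 0 with an estimated correlation (smallest adjusted p = 0.50), 16 by fry (16 upward, 0 downward) and 18 after alignment. The clock list did not pass (11 of 23 rose, list adjusted p = 0.118), nor did those of basement membrane, glycolysis, the small RNA pathway, p53, proteasome, insulin signalling, smooth muscle, neutrophils and mast cells, red cells, adipocytes, skeletal muscle, nerve and sex-linked genes. The count of genes was 2335 and 2055 without control-virus replicate 1 or 3, 7164 and 2840 without shRNA replicate 5 or 6, and 2624 with sex as a covariate. The control-virus mutants held no male, so in this pair of groups only shRNA replicate 8 shared their sex.

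**Figure D3:**
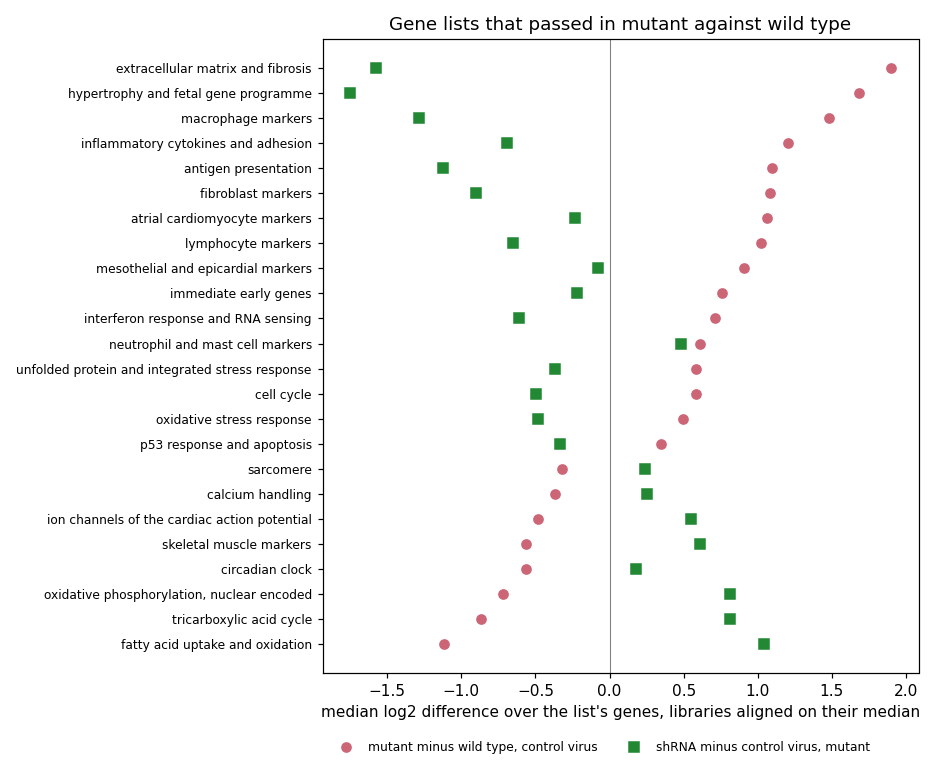
Median log2 difference over the genes of each list, libraries aligned on their median, for the 24 lists that passed between mutant and wild-type hearts by camera (0 with an estimated correlation, smallest adjusted p = 0.375, and 2 by fry). Circles are mutant minus wild type, both with control virus, and squares are shRNA label minus control virus in mutant hearts. The matrix list lies at 1.90 and -1.58 and the fatty acid list at -1.12 and 1.04. As deposited, 5 lists that lie below 0 here for the shRNA label had medians above 0 (unfolded protein, oxidative stress, immediate early, atrial and mesothelial), and so did the p53 list.

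The changes with the shRNA label ran against those of the mutant. Across 12980 genes the log2 differences of the comparisons had a Pearson r of -0.872 and a Spearman rho of -0.857, with a covariance of -0.356; genes are not independent replicates. Since both share the control-virus mutants with opposite sign, unchanged groups simulated 100 times gave a mean r of -0.536 and a covariance of -0.0516. With untreated mutants in place of the control-virus mutants in the mutant difference, no library was shared, and r was -0.776 and rho -0.770 (covariance -0.309, simulated 8.26e-05). Of 279 genes higher in the mutant 132 were lower with the shRNA label, and of 954 lower genes 929 were higher; 0 passed in the same direction in both by limma. After alignment the overlaps were 1024 of 1672 and 903 of 1472, and 0 passed in the same direction. These overlaps share the control-virus mutants, and no value for unchanged groups was computed for them. No p is given across genes.

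Hearts labelled shRNA and wild-type hearts were compared to see what still differed from wild type. Of 27 immediate early genes 3 passed (list adjusted p = 1.27e-08, and 0.424 with an estimated correlation): Atf3 (25.8 ± 6.36 against 7.10 ± 2.91 FPKM), Btg2 (78.2 ± 15.2 against 23.3 ± 5.19 FPKM) and Junb (64.4 ± 18.1 against 18.8 ± 0.729 FPKM) rose 3.37-fold, 3.26-fold and 3.20-fold, but did not pass aligned (adjusted p = 0.0748, 0.0682 and 0.0610). Cma1 (4.80 ± 1.04 against 0.603 ± 0.179 FPKM), the mast cell chymase, rose 3.59-fold, Wif1 (14.7 ± 8.91 against 2.16 ± 0.291 FPKM), a Wnt inhibitor, 4.4-fold, and Nxpe4, Abca4, Tescl, Prps2 and Slc41a3 3.01-fold to 4.39-fold (adjusted p = 0.00932 to 0.0409 over these 10 genes). In all 14 genes passed limma, 14 higher and 0 lower, with 2026 at an unadjusted p under 0.05 and a median of 0.34. After alignment 11 passed, 4 higher and 7 lower, of which Nxpe4, Prps2 and Slc41a3 were among the 14. The groups did not overlap for 1429 genes (11.0%, where chance gives 5.71%). Without shRNA replicate 8 the count was 218 (177 higher, 41 lower), and 746 with alignment as well. It was 0 and 2 without wild-type replicate 2 or 3, and 256 and 1 without shRNA replicate 5 or 6.

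Hearts labelled shRNA and untreated mutant hearts were compared to see what differed when the reference had no virus. Mylk4 (129.6 ± 70.9 against 7.23 ± 1.51 FPKM) and Rpl3l (638 ± 385 against 44.8 ± 32.3 FPKM), a kinase and a ribosomal protein of muscle, rose 13.6-fold and 12.6-fold, and Car14 (225 ± 118 against 17.7 ± 6.20 FPKM), a carbonic anhydrase, 10.5-fold. Pfkfb1, Efnb3, Lrrc4b, Gpt, Kcnj3 and Scd4 rose 10.3-fold to 12.0-fold. Stbd1 (3.81 ± 4.85 against 50.8 ± 5.91 FPKM), a glycogen-binding protein, fell 14.8-fold, the matrix protease Mmp3 (1.09 ± 1.97 against 14.8 ± 7.11 FPKM) 9.07-fold, and Leprel1, Nlrc3, Krt18, Syndig1, Adamts20, Mrap2 and Kcnj6 4.97-fold to 6.97-fold. Rpl35a rose 11.0-fold and Rpl26 fell 6.77-fold; both are ribosomal genes with close copies. Leaving out replicate 8, the folds of Rpl3l, Pfkfb1, Efnb3, Lrrc4b, Gpt, Kcnj3, Stbd1 and Leprel1 were 20.2-fold, 22.3-fold, 18.5-fold, 17.1-fold, 17.8-fold, 19.8-fold, 22.4-fold and 11.9-fold. In all 7113 genes passed limma, 6956 higher and 157 lower, with a median of 0.66; aligned, 3789 passed, 2067 higher and 1722 lower, and 1010 of the 7113 changed sign. The groups did not overlap for 5586 genes (43.0%, where chance gives 5.71%). The count was 4686 without untreated replicate 10, the library with the lowest scale, and 6861 without shRNA replicate 8.

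In the small RNA libraries, which address the same questions for microRNA genes, mutant hearts with control virus had 46.7 ± 9.58 against 1.81 ± 0.207 MFPKM (FPKM divided by 1e+06) of mmu-mir-208b, hosted by the slow myosin gene Myh7, as means ± SD over 3 mutant and 2 wild-type libraries. This is 25.5-fold higher without passing limma (adjusted p = 0.135). Also without passing, mmu-mir-21, reported in fibrosis, was 5.69-fold higher, mmu-mir-499, hosted by Myh7b, 2.58-fold lower and mmu-mir-208a, hosted by Myh6, 1.78-fold lower (adjusted p = 0.135, 0.179 and 0.135). With the smallest p values, mmu-mir-142, mmu-mir-497 and mmu-mir-148a were 2.15-fold, 1.96-fold and 1.69-fold higher and mmu-mir-328 1.72-fold lower (adjusted p = 0.105 each), and mmu-mir-199b was 2.4-fold higher and mmu-mir-215 4.98-fold lower. Of 280 genes 0 passed by limma, 35 had an unadjusted p under 0.05, and 79 had groups that did not overlap (28.2%, where chance gives at most 20%). The chance share in small RNA is an upper limit, since ties at 0 count as overlapping and only 134 genes were above 0 in every library. Adjusted over the list alone, 6 of 28 hypertrophy microRNAs, 3 of 7 muscle, 3 of 22 fibrosis, 2 of 11 endothelial, 1 of 10 blood and 0 of 12 let-7 genes passed. Without shRNA replicate 8, which enters only the shared spread, 19 passed (11 higher, 8 lower), among them mmu-mir-208b (adjusted p = 4.93e-05), mmu-mir-21 and mmu-mir-499. The count was 2 and 7 without wild-type replicate 2 or 3, which leaves 1 wild-type library assumed to vary like the other groups, and 2, 1 and 2 without control-virus replicate 1, 2 or 3.

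**Figure D4:**
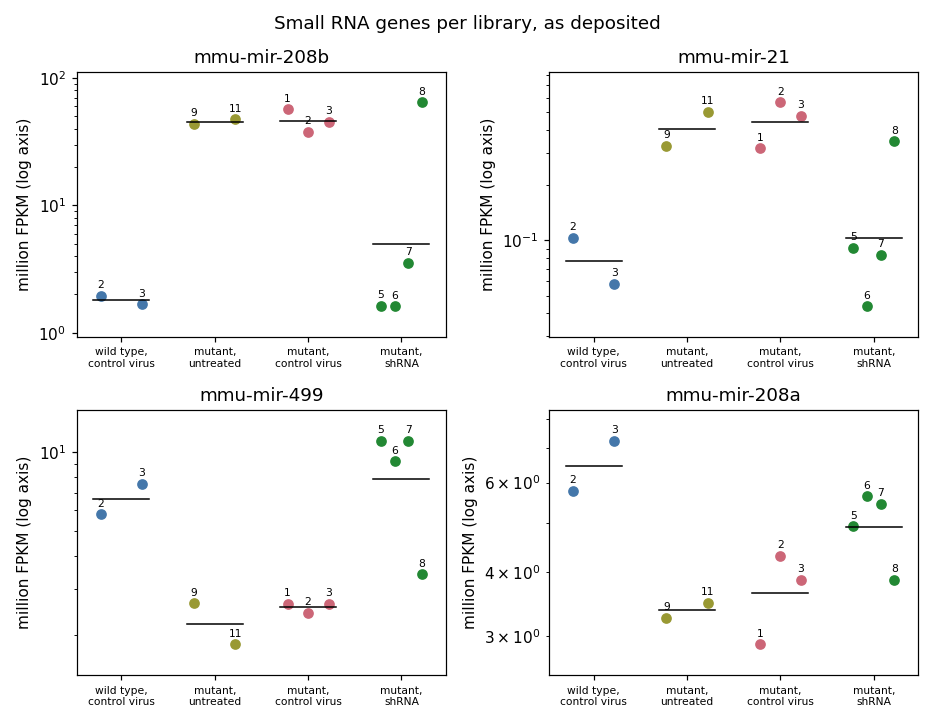
Level of 4 microRNA genes per small RNA library in MFPKM on a log axis, in the 4 groups; points are libraries with their replicate numbers and lines are geometric means. For mmu-mir-208b, shRNA replicates 5, 6 and 7 lie at 1.62, 1.62 and 3.56 MFPKM, wild-type replicates at 1.96 and 1.67, and shRNA replicate 8 at 64.5.

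With the shRNA label, mmu-mir-499 was 8.68 ± 3.62 against 2.56 ± 0.117 MFPKM (4 against 3 libraries), 3.08-fold higher without passing (adjusted p = 0.132). Without passing either, mmu-mir-208b was 9.31-fold lower (adjusted p = 0.213), mmu-mir-21 4.25-fold lower and mmu-mir-208a 1.35-fold higher (adjusted p = 0.148 and 0.331). With the smallest p values, mmu-mir-199b, mmu-mir-541, mmu-mir-130a, mmu-mir-434 and mmu-mir-500 were 1.47-fold to 4.44-fold lower and mmu-mir-204 5.48-fold higher. Also among these, mmu-mir-134 was at 0 in 3 of the 11 libraries. Without passing, mmu-mir-129-2 was 2120, 6850 and 14953 FPKM in control-virus mutant replicates 1, 2 and 3 and listed at 0 in the other 8 libraries. The abundant mmu-mir-29a differed 1.04-fold (adjusted p = 0.845), and mmu-mir-29c 1.11-fold. The rows mmu-mir-1-1, mmu-mir-133a-2, mmu-mir-29b-1 and mmu-mir-29b-2 were listed at 0 in 3, 7, 10 and 1 libraries, and none passed. Of 280 genes 0 passed by limma, 42 had an unadjusted p under 0.05 (smallest adjusted p = 0.0568), and 26 had groups that did not overlap (9.29%, where chance gives at most 5.71%). Adjusted over the list alone 2 of 7 muscle and 1 of 28 hypertrophy microRNAs passed, and 0 of the fibrosis, endothelial, blood and let-7 lists. Without shRNA replicate 8, 26 genes passed (11 higher, 15 lower), among them mmu-mir-499 (adjusted p = 8.44e-05) and mmu-mir-208b (21.9-fold lower, adjusted p = 2.84e-05). The count was 2 without control-virus replicate 1, 2 or 3 and without shRNA replicate 6, and 3 without shRNA replicate 7.

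Between control virus and no virus in mutant hearts (3 against 2 libraries) 0 of 280 small RNA genes passed by limma, 9 had an unadjusted p under 0.05, and 0 passed adjusted over any list alone. Sex was uneven between these groups as well. Among the smallest p values, mmu-mir-34a was 1.86-fold and mmu-mir-434 1.80-fold higher with the virus, and mmu-mir-328, mmu-mir-30d and mmu-mir-149 were 1.33-fold to 1.40-fold lower (adjusted p = 1 each). The others, mmu-mir-129-2, mmu-mir-879, mmu-mir-218-2, mmu-mir-376a and mmu-mir-1943, were listed at 0 in 8, 2, 1, 6 and 7 of the 11 libraries. Of these, mmu-mir-129-2 was above 0 only in the 3 mutant libraries with control virus. The groups did not overlap for 35 genes (12.5%, where chance gives at most 20%). Genes tied at 0 count as overlapping, so whether this share lies below chance cannot be told. The count was 12 and 3 without untreated replicate 9 or 11, which leaves 1 untreated library assumed to vary like the other groups, 2, 1 and 1 without control-virus replicate 1, 2 or 3, and 0 without shRNA replicate 8.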

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

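In this part the tests of shRNA replicate 8 and of the genotype of its group, of the matrix genes and of the clock genes, and the splits of the aligned values, were chosen after the result was seen; the splits of the values as deposited were planned. In the group labelled shRNA (4 libraries), the gap between the farthest library and its nearest neighbour was divided by the range of the group, and a share near 1 means that 1 library stands alone. Of 180 results tested in this way 30 stood out, and in 25 of them the farthest library was replicate 8. About 5% of independent, unselected results would stand out by chance. Many of these genes were named for group differences and all values come from the same 4 hearts, so the 30 cannot be set against that share.

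Replicate 8 stood alone by 0.959 of the range for Kcnj3, 0.835 for Wnt16, 0.932 for Krt18, 0.853 for Ppp2r2c, 0.833 for Ankrd1, 0.889 for Col1a1, 0.841 for Postn, 0.894 for Tnc, 0.921 for Thbs1 and 0.837 for Kdr. It did so by 0.922 for Sprr1a, 0.979 for Six3, 0.936 for Lgals3, 0.947 for Gpnmb, 0.941 for Smco1, 1 for Vaultrc5, 0.875 for Xirp2, 0.929 for Ddx3y, 0.902 for Eif2s3y, 0.864 for Adamts20 and 0.909 for Kcnj6. The same held for 0.845 in mmu-mir-499 and 0.881 in mmu-mir-204, for 0.977 in the polyA axis position and for 0.865 in the small RNA axis position with low values filtered. Replicate 7 stood alone for mmu-mir-134 (1) and mmu-mir-29b-1 (1), and replicate 6 for mmu-mir-142 (0.864), mmu-mir-376a (1) and mmu-mir-1943 (1). For Vaultrc5, mmu-mir-134, mmu-mir-29b-1, mmu-mir-376a and mmu-mir-1943 the other 3 libraries were listed at 0, so the share is 1 by construction and no evidence; all 5 are counted in the 30, and Vaultrc5 also in the 25.

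The first pattern is that shRNA replicate 8 lay with the mutant libraries. Its position was 0.687 as deposited and 0.871 after alignment, which argues against library scale, and the male untreated mutants lay at 0.862 or above on an axis made without them, which argues against sex. Its small RNA library lay at 0.984 with low values filtered, against 0.308 to 0.399 for replicates 5 to 7, which argues against an exchange of the polyA library alone, but with low values kept it lay at 0.381, beside replicate 6 of its group, so the position rests on the filter; mmu-mir-208b, at 64.5 MFPKM against 1.62 to 3.56 in replicates 5 to 7 and 37.9 to 56.9 in mutants with control virus, does not. A wrong treatment label, a vector that was not active or a heart that did not respond may apply to replicate 8 and cannot be told apart: the row named shRNA was at most 0 in every library, and hMyl2, at 228.8, 419.6 and 317.2 FPKM in replicates 5 to 7 and 0 in replicate 8, separates it from its group but was also 0 in every library of the other groups. A genotype other than the label's may as well apply to replicates 5 to 7, since Six3 was at most 0.0913 FPKM there, as in wild type, against 60.6 in replicate 8 and at least 13.6 in mutants without shRNA; a loss of Six3 in response to the shRNA would look the same, so this stays open.

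The second pattern is the lower level of matrix genes with the shRNA label, where sex and library scale differed between the groups. Among male libraries alone (3 labelled shRNA, 2 untreated; aligned) the median log2 difference of the 42 matrix genes was -1.44 with 41 of 42 below 0, which argues against sex as the whole cause. Against control virus the median of all genes was 0.47 higher with the shRNA label as deposited. Scale would thus raise the matrix genes, which argues against scale as the cause of their lower level. After alignment their median was -1.58 with 42 of 42 below 0. Alignment could only move this median further down, so that value is no separate test. That the shRNA lowers these genes stays a hypothesis, since it was found and tested on the same libraries, the transgene row gives no measure of knockdown, and a genotype other than the label's in replicates 5 to 7 is not excluded.

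The third pattern is the difference in clock genes between mutant and wild-type hearts. An index of 6 output genes over Arntl, Npas2 and Nfil3 was 2.27 lower in mutant hearts with control virus on the log2 scale. Library scale cancels in this index except for the 1 added to each FPKM, so the difference argues against scale as the whole cause. The index varied by 1.01 within wild type, 0.449 and 0.892 within mutants with control virus and without virus, and 2.48 within the hearts labelled shRNA. A different time of day at which hearts were taken may contribute and cannot be told apart from genotype, because the labels give no time and all hearts of a group could have been taken at 1 time. No biological explanation was tested.

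Splits of the same libraries into groups of the same sizes were counted. For shRNA against control virus 3 of 35 splits gave as many genes as the real 4545 (highest other 7631, with shRNA replicate 5 placed among the control-virus libraries), and aligned 2 of 35 (3128, highest other 6475, with replicate 8 placed there). Against untreated mutants these were 2 of 35 (7113, highest other 9255, with replicate 5 moved) and aligned 2 of 35 (3789, highest other 6461, with replicate 8 moved). Against wild type they were 4 of 35 (14, highest other 4431, with replicate 5 moved) and aligned 2 of 35 (11, highest other 542, with replicate 8 moved), several times the real counts, which points to a structure of the samples, whose cause these splits do not show. Lists gave 12 of 35 (22, highest other 25) and the correlation without a shared library 3 of 35 (-0.776, lowest other -0.792). In none of these comparisons can chance be excluded by this count. In small RNA the real count was 0 (highest other 32, with replicate 8 moved), so all 35 of 35 splits are as large by construction and nothing follows from them.

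For the comparisons of 3 against 3 libraries the splits are too few for a share under 5%. Mutant against wild type gave 1233 genes (highest other 1; 1 of 10 splits as large), aligned 3144 (highest other 1; 1 of 10) and 24 lists (highest other 22; 1 of 10). Control virus against no virus gave 0 genes (highest other 1; 10 of 10), aligned 0 (highest other 1; 10 of 10) and 6 lists (highest other 18; 10 of 10); a real count of 0 makes every split as large by construction.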

How the results depend on the processing

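Tests with alignment, with sex as a covariate, with the small RNA pseudocount of 1000, and without shRNA replicate 8 where it is in neither group were chosen after the result was seen; the others were planned. Of the counts and correlations that answer a comparison, 117 alternatives stayed within 1.5 times the reported count or within the spread and 80 did not. Of the named genes 3445 alternatives stayed on the same side of the threshold. Another 466 no longer passed (225 of them with a library left out), 169 newly passed and 0 turned. Of the lists 1499 stayed, 161 no longer passed, 92 newly passed and 12 turned. Direction was compared only where the reported or the alternative test passed, so items that passed in neither count as stayed whatever their direction. The cause was not tested except where named, and unknown read depth limits all values.

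For shRNA against control virus 2406 genes passed with the 2 groups alone, 2624 with sex and 1879 with sex and without replicate 8; with a library left out 2055 to 7164. The split of higher and lower genes followed the scaling: 4330 and 215 as deposited, 1662 and 1514 with quantile normalization, 820 and 2351 with equal totals. For mutant against wild type 796 genes passed with no filter (more genes tested), 3386 with quantile normalization, 2603 with equal totals (1617 higher, 986 lower), 3597 with the 2 groups alone, 3144 aligned, 5156 aligned without replicate 8, 2755 without it and 126 with sex; with a library left out 179 to 2755. With the replicate block 804 passed (537 higher, 267 lower; 453 shared with the reported genes, residual df 1); equal numbers are different animals, the deviations of same-number libraries were correlated at -0.196 and -0.107, and the unpaired fit is reported. The small RNA block gave 0 by limma (40 at an unadjusted p under 0.05).

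For control virus against no virus 1 gene passed with no filter, 181 with the 2 groups alone, 7 without replicate 8, 6 aligned without it and 3 with sex without it; with a library left out 0 to 7. For shRNA against wild type 0 passed with the 2 groups alone by limma (1316 at an unadjusted p under 0.05), 50 with sex, 746 aligned without replicate 8 and 211 with sex without it; with a library left out 0 to 256. For shRNA against no virus 3707 passed with quantile normalization, 4598 with equal totals (1029 higher, 3569 lower) and 3789 aligned; with a library left out 4686 to 9067.

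In small RNA 1 gene passed for shRNA against control virus with no filter, 1 with the 2 groups alone, 1 with robust eBayes and 37 with the pseudocount of 1000 without replicate 8; with a library left out 0 to 26. For mutant against wild type, with only 2 wild-type libraries, these were 2 with equal totals, 6 with the 2 groups alone and 24 with the pseudocount of 1000 without replicate 8; with a library left out 1 to 19. For control virus against no virus a library left out gave 0 to 12.

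Lists that passed numbered 0 with an estimated correlation for shRNA against control virus, and 0 for mutant against wild type, where fry gave 2 (0 upward); with a library left out they were 22 to 24 and 23 to 26. For control virus against no virus they were 2 with no filter, 15 with sex, 1 with an estimated correlation, 0 by fry, 10 without replicate 8, and 5 to 12 with a library left out. Lists that turned direction were, for shRNA against control virus, sarcomere with quantile normalization (adjusted p = 0.816) and by fry unfolded protein (0.848), oxidative stress (0.848), immediate early (0.425), atrial (0.795) and sex-linked genes (0.0388). For mutant against wild type skeletal muscle turned with no filter (0.880). For control virus against no virus, with sex, matrix (0.0146), fatty acid (2.63e-05) and lymphocyte (0.0205) lists turned, and by fry hypertrophy and heat shock (0.892 each). With sex as a covariate and shRNA replicate 8 left out, none of the lists turned. The correlation of the differences was -0.776 with no shared library and -0.887 to -0.839 with a library left out.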

Other observations

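The list tests in this part were chosen after the result was seen. Between hearts labelled shRNA and wild-type hearts, 10 of 36 lists passed by camera, 3 upward and 7 downward, 0 with an estimated correlation (smallest adjusted p = 0.0645), 2 by fry and 5 after alignment. Of the 10 lists 3 also passed aligned: neutrophils and mast cells and immediate early genes upward and heat shock downward. The other 7, oxidative phosphorylation upward and hypertrophy, ion channels, clock, smooth muscle, adipocytes and sex-linked genes downward, did not (aligned adjusted p = 0.147 to 0.946). Of 8 neutrophil and mast cell markers 6 rose adjusted over the list alone and 1, Cma1, over all genes; the proteases Tpsb2 and Mcpt4 were 5.10 ± 2.19 against 0.848 ± 0.192 FPKM and 8.49 ± 4.85 against 1.26 ± 0.511 FPKM (mean ± SD, 4 against 3 libraries). Neither passed over all genes (adjusted p = 0.0806 and 0.101 by limma). Replicate 8, at 3.87 and 3.03 FPKM of these genes, lay above the wild-type libraries as replicates 5 to 7 did, but 1 mutant heart with control virus had 3.21 and 3.62 FPKM, and 0 of the 8 markers rose over all genes after alignment. The list adjusted p was 1.18e-08, and 0.0645 with an estimated correlation. Of 27 immediate early genes 15 rose over the list alone, 3 over all genes and 0 over all genes after alignment (list adjusted p = 1.27e-08, and 0.424 with an estimated correlation). Markers of mast cells are few and low in whole heart, and no count of cells was made.

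Heat shock genes passed downward as a list against wild type (18 genes, median log2 difference -0.11, aligned -0.46; list adjusted p = 5.80e-11, and 0.553 with an estimated correlation), with 0 members passing by limma, over the list alone as well. Hsph1, a chaperone of the Hsp110 family, was 34.8, 71.5 and 67.2 FPKM in shRNA replicates 5 to 7 and 293.8 in replicate 8, against 150.9, 284.9 and 200.5 in wild-type libraries. Smooth muscle actin Acta2, also a marker of activated fibroblasts, was 34.5, 55.1 and 62.5 FPKM in replicates 5 to 7 and 1059 in replicate 8, against 117, 159 and 278 in wild type. In mutant hearts it was 449.9, 373 and 662 FPKM without virus and 649, 1012 and 705 with control virus. Acta2 and Hsph1 were chosen after their values were seen.

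Against untreated mutant hearts 22 of 36 lists passed by camera, 5 upward and 17 downward (17 of the 22 also aligned), 0 with an estimated correlation (smallest adjusted p = 0.368) and 18 by fry, with the 47 oxidative phosphorylation genes up (47 rose, 45 aligned) and 4 matrix genes of 42 down (27 aligned). Their adjusted p was 0.475 each with an estimated correlation.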
